A study of Danio rerio with 24 samples.

How the data were processed

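RNA from zebrafish at 120 hpf was sequenced in 24 libraries, 4 for each combination of 3 PFHxS doses (0, 0.0025 and 25 µM, each in 0.1% DMSO) and 2 photoperiods (24 h dark, or 14 h light and 10 h dark). Per the labels, exposure ran from 0.75 hpf to collection at 120 hpf. The treatment description names dark conditions for all samples, while 12 titles give the light-dark cycle, and the titles were followed. The 12 dark libraries belong to one library series and the 12 cycle libraries to another, so photoperiod and library series coincide. The number of larvae per library, the clutches and the clock time of collection are not given.

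Reads were aligned with HISAT2 2.0.5 and counted over genes with featureCounts 1.5.0-p3, per the submitters' processing notes. The authors deposited gene-level FPKM (fragments scaled by gene length and library size) in 2 tables, 1 per photoperiod, with 32520 genes each. The genome build and annotation release are not given in the sources used here, and coordinates are printed as the tables give them. The extraction protocol describes directional and non-directional libraries without saying which were made, so genes that overlap on opposite strands and near-identical paralogs may share fragments. Multiplying the deposited FPKM by gene length gave whole multiples of 1 step per library for 100% of values above 0 (tolerance 0.001), which allowed the number of fragments per gene to be recovered. The scale of each dark library was proportional to median-of-ratios size factors over the 12 dark libraries, and that of the cycle libraries lay within 0.98661 to 1.0202 of such factors over their own 12, so the tables had been scaled separately. All 24 value columns were assigned to a sample, and no pair of libraries was identical. Dates had replaced 12 gene symbols in both tables, and these genes were followed by their identifiers.

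The design had set a test for raw counts and a second test in case only FPKM was available, and the second was used because the tables hold FPKM. Values were analysed as log2(FPKM + 0.1) in R 4.3.3 with limma 3.58.1 (linear models with empirical Bayes moderation and an intensity trend). Genes needed an FPKM of at least 0.5 in at least 4 libraries, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05 and no fold minimum. Contrasts within a photoperiod (25 µM against control, 0.0025 µM against control, 25 µM against 0.0025 µM) were fitted on its 12 libraries. The differences between photoperiods in the effect of each dose, and dark controls against cycle controls, were fitted on all 24 libraries with 1 mean per group, with FPKM set across the tables. A gene-wise offset between the library series cancels in the first 2 of these and not in the last.

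Gene lists (40 lists, 1310 of 1373 members matched to the tables) covered the clock, light response, eye, liver, lipid, endocrine, stress, immune, cell cycle and tissue marker genes, and included ribosomal and mitochondrially encoded transcripts. Each list with at least 5 tested members was tested with limma camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Members were also adjusted over the list alone. The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. By that rule each comparison names, among genes past the threshold with a mean FPKM of at least 1, a gene symbol that is no placeholder and groups that do not overlap (in contrasts of 2 groups), the 10 largest rises and the 10 largest falls. It adds up to 4 members per list with the smallest adjusted p, or the 2 most abundant where none passed. Where fewer than 10 genes passed all were named, and where none passed the 6 with the smallest p. The genes per1a, per2, cry5, nr1d1, pparaa, cpt1aa, pdk4, fabp10a, cyp1a, dio3b and opn1lw2 were given throughout.

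Log2 values of libraries of the same group correlated with r from 0.930 to 0.958. The procedure was tested on simulated data drawn from the means of the real libraries, with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. For 25 µM in darkness it recovered 23.9%, 50.7% and 87.9% of them with 8 unchanged genes called, for 25 µM under the cycle 31.3%, 55.2% and 86.4% with 10, and for the difference between these effects 16.4%, 40.3% and 77.3% with 5. Alternatives were limma-voom on the recovered fragments, a pseudocount of 1, no expression filter, a mean of at least 50 fragments, a fold threshold of 1.2, the replicate number as a block, only the 2 groups compared, all 24 libraries in 1 fit, and each library left out in turn. Scaling to total fragments and median-of-ratios factors over the libraries of each fit were added after the data were seen. Tests that need raw counts as deposited were not used since the values are not counts. A result for 1 gene that the naming rule selected is not reported here.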

Results

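Gene expression was measured by RNA sequencing in wild-type zebrafish (Danio rerio), labelled as whole embryos and collected at 120 hours post fertilisation (hpf), a free-swimming larval stage. The fish had been exposed since 0.75 hpf to perfluorohexane sulfonate (PFHxS), a fluorinated surfactant that persists in the environment, at 0, 0.0025 or 25 µM with 0.1% dimethyl sulfoxide (DMSO) as vehicle. Each dose was combined with constant darkness (24 h dark) or a cycle of 14 h light and 10 h dark, which gave 6 groups of 4 libraries, 24 in all. The series title asks whether a disturbed photoperiod alters the developmental toxicity of PFHxS. The photoperiod was taken from the sample titles, because the treatment description speaks of darkness for every sample. The 12 dark libraries held 8.44 to 14.5 M fragments counted over genes (median 9.05 M), and the 12 cycle libraries held 10.1 to 18.5 M (median 12.2 M). Mitochondrially encoded transcripts took 5.15% ± 0.22 (SD, n = 4) of fragments in cycle controls and 5.89% ± 0.088 in the cycle group at 25 µM, against 5.38% ± 0.26 and 5.32% ± 0.10 in the corresponding dark groups. Nothing in the labels says that replicates came from separate clutches, so all p-values measure only the spread between these samples, which may be technical.

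Exposure to 25 µM PFHxS in constant darkness lowered all 41 measured members of the cell cycle and DNA replication list, with a median log2 fold change of −1.39 (n = 4 per group). The list had an adjusted p = 0.0789 with an estimated correlation. Rises included il11a, a cytokine of the interleukin-6 family (chromosome 16, 12611362 to 12617155), with a log2 fold change of 6.15 ± 0.78 (SE, limma adjusted p = 0.000161), and cyp2k6, a cytochrome P450 (chromosome 3, 12816362 to 12826387), at 5.19 ± 0.36 (adjusted p = 2.09e-06). In level, cyp2k6 went from 0.0532 ± 0.045 FPKM (SD) in controls to 5.45 ± 1.45 at 25 µM, and il11a from 0.176 ± 0.35 to 15 ± 11.1. At such control levels the fitted values depend on the added 0.1 FPKM. With a pseudocount of 1 they were 2.59 for cyp2k6 and 3.52 for il11a. In all, 4147 of 19058 tested genes passed an adjusted p of 0.05, 2318 higher and 1829 lower, of which 570 and 407 changed at least 2-fold. Scaled to total fragments, 2128 were higher and 2117 lower.

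In the cell cycle list the replication licensing gene mcm2 (chromosome 22, 5632029 to 5655680) went from 15 ± 1.22 to 5.47 ± 1.88 FPKM, a log2 fold change of −1.5 ± 0.19 (adjusted p = 0.000144). Changes of the same kind were seen in the mitotic topoisomerase top2a (−1.56 ± 0.19), the cyclin ccna2 (−1.78 ± 0.20) and the mitotic kinase aurkb (−1.58 ± 0.18), each with an adjusted p of 0.000124 or below. Adjusted over the list alone, all 41 members were also lower, and camera placed the list below other genes (adjusted p = 8.48e-28, and adjusted p = 0.0789 with an estimated correlation). The kinetochore gene cenph, outside the list, fell by 2.14 ± 0.35. Of 36 extracellular matrix, cartilage and bone genes 19 fell, 1 rose and 16 did not pass. The falls included col10a1a (−0.65 ± 0.11), col9a1a (−0.60 ± 0.089) and epyc (−0.75 ± 0.14), which encode cartilage matrix proteins. Adjusted over the list alone 23 were lower and 2 higher. The matrix list had a camera adjusted p of 2.81e-07, and adjusted p = 0.25 with an estimated correlation. Of 32 keratinocyte and epidermis genes 17 fell and 1 rose, including icn2 (−1.34 ± 0.26), ppl (−0.74 ± 0.13) and evplb (−0.57 ± 0.11). Adjusted over the list alone 20 were lower and 2 higher. The epidermis list had a camera adjusted p of 8.02e-06, and adjusted p = 0.162 with an estimated correlation.

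In the list of the glucocorticoid axis and its targets 14 of 21 members rose and none fell, and adjusted over the list alone 15 rose. The glucocorticoid list had a camera adjusted p of 3.22e-07, and adjusted p = 0.0973 with an estimated correlation. The pituitary hormone precursor pomcb, with a mean of 1 fragment per control library, showed a log2 fold change of 4.75 ± 0.72 and reached 5.59 ± 1.97 FPKM. The corticotropin-releasing hormone gene crhb rose by 1.97 ± 0.15 (adjusted p = 3.2e-06), the kinase sgk1 by 1.44 ± 0.11 (adjusted p = 4.04e-06) and the gluconeogenic enzyme pck1 by 1.23 ± 0.14, from 294 ± 48.5 to 684 ± 58.1 FPKM. In the monoamine and neuropeptide list 15 of 41 members rose and 2 fell (17 and 3 adjusted over the list alone), with galn at 2.19 ± 0.25 and vip at 1.4 ± 0.16. The neuropeptide list had a camera adjusted p of 0.00203, and adjusted p = 0.113 with an estimated correlation. Among 41 synapse and neuronal activity genes 16 rose and 5 fell, and adjusted over the list alone 16 and 7. The members with the smallest p were immediate early genes, which neurons and other cells switch on within minutes of a stimulus: npas4a (3.21 ± 0.26), nr4a3 (2.25 ± 0.11, adjusted p = 7.76e-08), ier2a (1.72 ± 0.13) and fosl1a (3.75 ± 0.27). The list stood above other genes with a camera adjusted p of 0.0012 and an adjusted p = 0.249 with an estimated correlation. Parathyroid hormone pth1a rose by 4.92 ± 0.72 to 12.6 ± 4.05 FPKM, and the leptin gene lepb by 3.76 ± 0.68 to 3.98 ± 2.15 FPKM. With a pseudocount of 1 the values were 2.47 for pomcb, 3.25 for pth1a and 1.94 for lepb.

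Of 27 heat shock genes 16 rose and 1 fell at 25 µM in darkness, and adjusted over the list alone 16 rose and 2 fell. The heat shock list had a camera adjusted p of 7.27e-08, and adjusted p = 0.117 with an estimated correlation. The small heat shock genes hspb9 and hspb11 rose by 4.05 ± 0.36 and 2.67 ± 0.18, and the chaperone hsp90aa1.1 by 1.78 ± 0.14. The rises of hsp70.1 (3.69 ± 0.62) and hsp70l (3.69 ± 0.78) came with wide spread, 32.8 ± 37.2 and 53.5 ± 58.4 FPKM at 25 µM, and that of hsp70l ended in a limma-voom fit. Both belong to a family of near-identical copies whose fragments may have been split in counting. In the unfolded protein and amino acid stress list 17 of 33 rose and none fell, also adjusted over the list alone, including the transcription factors atf3 (2.54 ± 0.22) and ddit3 (1.38 ± 0.12), trib3 (1.4 ± 0.14) and ddit4 (1.62 ± 0.21). Its camera adjusted p was 5.83e-08, with an adjusted p = 0.113 with an estimated correlation. Of 26 p53 and apoptosis genes 13 rose and none fell, also adjusted over the list alone, including pmaip1 (1.77 ± 0.20) and btg2 (1.56 ± 0.27). The p53 list had a camera adjusted p of 8.53e-05, and adjusted p = 0.113 with an estimated correlation. Of 34 innate immune genes 13 rose and none fell (13 higher and 2 lower adjusted over the list alone), with mmp9 at 2.31 ± 0.28, ptgs2a at 1.23 ± 0.15 and ptgs2b at 1.24 ± 0.18. The innate immune list had a camera adjusted p of 0.000139, and adjusted p = 0.25 with an estimated correlation. Of 35 NRF2 oxidative stress genes 14 rose and 5 fell (16 and 5 adjusted over the list alone). The rises included the glutathione synthesis gene gclm (1.15 ± 0.12), taldo1 (0.60 ± 0.061) and the autophagy receptor sqstm1 (2.52 ± 0.29), while prdx4 fell by 0.68 ± 0.073. This list had a camera adjusted p of 0.00996 and an adjusted p = 0.0789 with an estimated correlation.

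Of 29 PPAR signalling targets 13 rose in darkness, 3 fell and 13 did not pass (14 and 3 adjusted over the list alone). The lipase inhibitor angptl4 rose from 39.9 ± 2.55 to 97.3 ± 11.1 FPKM (1.28 ± 0.096, adjusted p = 3.36e-06). The carnitine palmitoyltransferases cpt1b and cpt1ab rose by 1.70 ± 0.14 and 1.22 ± 0.13, and the kinase pdk4 by 1.29 ± 0.14. The fatty acid binding gene fabp3 rose by 0.99 ± 0.090, whereas the fatty acid transporter cd36 fell by 0.96 ± 0.098. The receptor gene pparaa (−0.13 ± 0.14, adjusted p = 0.563) and the liver form cpt1aa (0.01 ± 0.095, adjusted p = 0.936) did not pass. The list's camera adjusted p was 0.00574, with an adjusted p = 0.0789 with an estimated correlation. Of 33 beta-oxidation genes 10 rose and 4 fell (12 and 6 adjusted over the list alone), with acadvl at 1.19 ± 0.11 (camera adjusted p = 0.00996, and adjusted p = 0.0789 with an estimated correlation). Of 33 insulin and glucose metabolism genes 17 rose and 6 fell (21 and 7 adjusted over the list alone). The glycolytic enzyme pfkma rose by 2.01 ± 0.099 (adjusted p = 9.45e-08), irs2b by 1.03 ± 0.11, and the growth factor binding genes igfbp1a and igfbp1b by 2.45 ± 0.26 and 3.44 ± 0.38. The insulin list had a camera adjusted p of 6.21e-05, and adjusted p = 0.0789 with an estimated correlation. Of 32 hypoxia response genes 16 rose and 1 fell (20 and 2 adjusted over the list alone), with ldha at 1.19 ± 0.085. The hypoxia list had a camera adjusted p of 7.06e-08, and adjusted p = 0.113 with an estimated correlation. Of 60 nuclear genes for oxidative phosphorylation 32 rose and none fell (41 and 0 adjusted over the list alone), each named one by less than 2-fold: uqcrc2b by 0.68 ± 0.054, cyc1 by 0.66 ± 0.060, uqcrfs1 by 0.66 ± 0.064 and sdha by 0.61 ± 0.057. Their camera adjusted p was 5.07e-13, with an adjusted p = 0.113 with an estimated correlation. Of the 13 mitochondrially encoded transcripts none rose and 2 fell, 0 adjusted over the list alone, with mt-nd5 at −0.24 ± 0.071, a call lost in 3 alternative settings and with any of 5 libraries left out.

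Of 34 hepatocyte genes 9 rose and 12 fell (9 and 13 adjusted over the list alone, camera adjusted p = 0.291). The secreted glycoprotein genes ahsg1 and ahsg2 fell by 3.36 ± 0.35 and 3.48 ± 0.27, and haptoglobin hp by 0.75 ± 0.11, while the glyoxylate enzymes agxta and agxtb rose by 0.86 ± 0.092 and 1.18 ± 0.14. The liver fatty acid binding gene fabp10a did not pass (0.05 ± 0.20, adjusted p = 0.887). In the complement and acute phase list 2 of 30 rose and 7 fell (3 and 8 adjusted over the list alone, camera adjusted p = 0.315), with the iron hormone hamp higher by 3.48 ± 0.41. Of 40 xenobiotic metabolism genes 11 rose and 5 fell (12 and 6 adjusted over the list alone, camera adjusted p = 0.103). They included the receptor nr1i2 (1.12 ± 0.13) and the sulfotransferase sult2st1 (1.12 ± 0.13), whereas cyp1a, a target of the aryl hydrocarbon receptor, stood at 0.01 ± 0.10 (adjusted p = 0.951). The cytochrome P450 pair cyp2aa8 and cyp2aa9 fell by 2.5 ± 0.38 and 2.28 ± 0.38. Of 29 intestinal brush border genes 9 fell and none rose (11 and 1 adjusted over the list alone), such as lactase lct (−1.27 ± 0.15) and the peptide transporter slc15a1a (−0.97 ± 0.12). The intestine list had a camera adjusted p of 0.000261, and adjusted p = 0.25 with an estimated correlation. Of 25 exocrine pancreas genes 7 fell and 2 rose (9 and 2 adjusted over the list alone), with ela2 at −1.01 ± 0.19 and cpa4 at −0.73 ± 0.15. The pancreas list had a camera adjusted p of 0.00526, and adjusted p = 0.564 with an estimated correlation.

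Of 26 ionocyte and kidney genes 8 rose and 2 fell (9 and 2 adjusted over the list alone), with the ammonium transporter rhcgb at 1.74 ± 0.16 and the phosphate transporter slc34a2a at −1.12 ± 0.096. The ionocyte list had a camera adjusted p of 0.0154, and adjusted p = 0.25 with an estimated correlation. Of 12 light-induced and photorepair genes 5 rose (5 adjusted over the list alone), with hif1al at 1.0 ± 0.095 and a camera adjusted p of 0.0338, or adjusted p = 0.113 with an estimated correlation. The clock repressor and output list had 5 of 24 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.118): per2 rose by 1.05 ± 0.17, cry3b by 0.69 ± 0.11 and bhlhe40 by 0.44 ± 0.063. In contrast, per1a (−0.03 ± 0.087, adjusted p = 0.821) and nr1d1 (0.09 ± 0.12, adjusted p = 0.623) did not pass. The activator limb of the clock had 1 of 9 lower (0 adjusted over the list alone). Of 22 cone phototransduction genes 6 fell and 1 rose, also adjusted over the list alone, with the ultraviolet opsin opn1sw1 at −0.61 ± 0.12 and the cone transducin gnat2 at −0.46 ± 0.10 (camera adjusted p = 0.0772), while the red opsin opn1lw2 was at −0.03 ± 0.28 (adjusted p = 0.962). Rod genes had 1 higher and 1 lower of 20, visual cycle genes 2 and 2 of 18, and lens crystallins 0 of 33, with crybb1 at −0.02 ± 0.065 and crygm2d13 at −0.11 ± 0.073. The last 3 lists gave the same counts adjusted over the list alone. The thyroid axis had 7 higher and 2 lower of 19 (7 and 3 adjusted over the list alone, camera adjusted p = 0.315), with thyrotropin-releasing hormone trh at 1.84 ± 0.18 and the deiodinase transcript dio3b at 1.24 ± 0.14.

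Of the remaining lists, the 68 cytosolic ribosomal protein genes had 2 higher and 4 lower (1 and 0 adjusted over the list alone) with a median of −0.121, a camera adjusted p of 0.000245 and an adjusted p = 0.654 with an estimated correlation. The counts of genes higher and lower were 8 and 4 of 24 for fatty acid and triglyceride synthesis, where lpin1 rose by 1.08 ± 0.15, 1 and 1 of 25 for cholesterol synthesis, 2 and 0 of 16 for bile acids, and 2 and 3 of 18 for apolipoproteins. The apolipoprotein apoeb rose by 0.70 ± 0.077 and apoa1b fell by 0.45 ± 0.11. They were 4 and 3 of 48 for muscle, 4 and 0 of 25 for haemoglobin and haem synthesis, 3 and 5 of 19 for myelin, and 5 and 4 of 33 for pigment cells, where the xanthophore gene tspan36 rose by 2.84 ± 0.44. Adjusted over the list alone these counts were 9 and 5, 1 and 1, 1 and 0, 3 and 4, 4 and 3, 4 and 0, 4 and 5, and 5 and 4 in the same order, and none of these 8 lists passed with camera (adjusted p from 0.238 to 0.979). List medians differed in sign from the mean or the camera direction for the clock activator, cholesterol, apolipoprotein, muscle and mitochondrially encoded lists. Outside the lists, falls also included the hatching enzyme gene he1.1 (−3.67 ± 0.75, a call lost in a limma-voom fit), the water channel aqp8b (−3.29 ± 0.52), the deoxycytidine kinase dck (−2.40 ± 0.33), aep1 (−2.18 ± 0.47) and sdr42e2 (−2.12 ± 0.64), the last a call lost in 2 settings and with any of 4 libraries left out. The microRNA precursor dre-mir-129-2 rose by 4.61 ± 1.16, on a mean of 10 fragments per library at 25 µM and 0.5 in controls. Over all 19058 tested genes, 4809 had all 4 libraries of one group above all 4 of the other, which chance gives for 2.86% of genes.

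**Figure D1:**
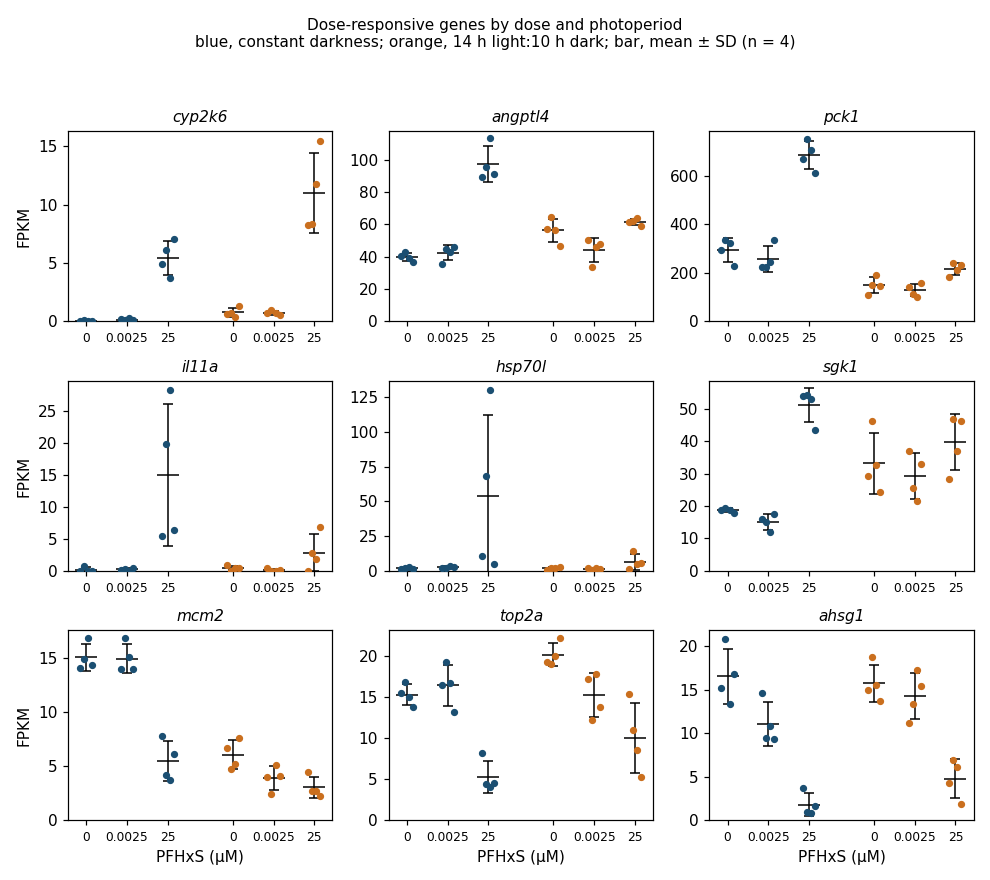
FPKM (y axis, linear, from 0) of 9 genes against PFHxS dose in µM (x axis), with 1 point per library, blue for constant darkness and orange for the light-dark cycle, and bars at mean ± SD (n = 4; bars are clipped at 0 where the SD exceeds the mean). In darkness angptl4 goes from 39.9 ± 2.55 to 97.3 ± 11.1 and mcm2 from 15 ± 1.22 to 5.47 ± 1.88 at 25 µM, and the points at 0.0025 µM lie near those of the controls.

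Under the light-dark cycle, 25 µM PFHxS raised the cytochrome P450 genes cyp2k6 and cyp2k18 and the GTPase gene arf4b, and lowered members of the hepatocyte and cone lists. Rises included arf4b, a small GTPase of vesicle traffic (chromosome 11, 42466834 to 42472941), from 3.77 ± 0.78 to 128 ± 62.1 FPKM (log2 fold change 4.91 ± 0.36, SE, n = 4, limma adjusted p = 8.04e-05), cyp2k6 (3.69 ± 0.30, adjusted p = 0.000197) and its neighbour on chromosome 3, cyp2k18 (2.38 ± 0.14, from 19.8 ± 3.63 to 104 ± 18.1 FPKM). Falls included ahsg2 (−3.28 ± 0.46) and leg1.1 (−1.88 ± 0.26), a gene of a liver-enriched secreted family. Of 18917 tested genes 328 passed, 209 higher and 119 lower, of which 47 and 54 changed at least 2-fold.

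Other rises under the cycle were in prl2, which encodes a prolactin-like hormone (2.58 ± 0.46), the desaturase scd (2.33 ± 0.50), the small heat shock gene hspb6 (2.17 ± 0.26), igfbp1b (2.14 ± 0.41) and the lipase inhibitor g0s2 (2.11 ± 0.34). Higher as well were dpagt1, an enzyme that starts N-glycan assembly (2.06 ± 0.21), and the small GTPase rab43 (2.00 ± 0.28). Other falls were in leg1.2 (−2.57 ± 0.55, a call lost in 3 settings and with any of 6 libraries left out), ahsg1 (−1.84 ± 0.32) and ponzr10 (−1.75 ± 0.32). Lower too were the green opsin opn1mw2 (−1.73 ± 0.15, adjusted p = 0.000251), the protease inhibitor serpina1l (−1.60 ± 0.27), the chitinase chia.3 (−1.57 ± 0.28), the clock-related repressor nfil3-6 (−1.56 ± 0.27) and the defensin defbl1 (−1.53 ± 0.26). The opsin, ahsg, leg1 and cyp2k genes have close paralogs, so their values are uncertain where fragments could be assigned to either copy. Of 34 hepatocyte genes 9 fell and 2 rose (16 and 3 adjusted over the list alone), with the complement gene c9 at −0.80 ± 0.095 and fabp10a higher by 0.63 ± 0.13 (adjusted p = 0.0379, a call lost in 5 settings and with any of 6 libraries left out). The list had a camera adjusted p of 2.99e-08 and an adjusted p = 0.159 with an estimated correlation. Complement and acute phase genes had 3 of 29 lower (8 adjusted over the list alone), including c8b (−0.85 ± 0.14) and crp3 (−1.05 ± 0.23). The complement list had a camera adjusted p of 3.62e-05, and adjusted p = 0.141 with an estimated correlation. Of 21 cone genes 3 fell (8 adjusted over the list alone): opn1mw2, pde6ha (−1.49 ± 0.16) and grk7a (−0.99 ± 0.18), while opn1lw2 stood at −0.63 ± 0.40 (adjusted p = 0.484). The cone list had a camera adjusted p of 3.52e-05 and an adjusted p = 0.192 with an estimated correlation.

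Cell cycle genes under the cycle had a median log2 fold change of −0.864 over 42 members, of which ccnb2 (−1.29 ± 0.27) and top2a (−1.09 ± 0.25) passed and 32 passed adjusted over the list alone. Camera gave an adjusted p of 1.63e-19, with an adjusted p = 0.192 with an estimated correlation. Xenobiotic metabolism had 3 of 38 higher and 2 lower (6 and 2 adjusted over the list alone): sult2st1 rose by 0.48 ± 0.10, and cyp1a fell by 0.49 ± 0.092 (adjusted p = 0.0257), with a camera adjusted p of 0.00168 for the list and an adjusted p = 0.141 with an estimated correlation. PPAR targets had 3 of 29 higher and 1 lower (7 and 1 adjusted over the list alone), with malic enzyme me1 at 1.37 ± 0.15, cpt1b at 0.65 ± 0.11, fabp3 at 0.46 ± 0.10 and ehhadh at −0.82 ± 0.15. The genes pdk4 (0.71 ± 0.29, adjusted p = 0.24), cpt1aa (0.11 ± 0.082, adjusted p = 0.575) and pparaa (0.12 ± 0.11, adjusted p = 0.67) did not pass. That list's camera adjusted p was 0.00603, with an adjusted p = 0.141 with an estimated correlation. Hypoxia genes had 2 of 29 higher (7 adjusted over the list alone), with ldha at 0.71 ± 0.079, and heat shock genes 1 of 26 (10 adjusted over the list alone), with hspb11 at 1.22 ± 0.27. Their camera adjusted p were 5.72e-06 and 6.52e-06, with an adjusted p = 0.141 and an adjusted p = 0.192 with an estimated correlation. NRF2 genes had 4 of 34 higher (9 higher and 1 lower adjusted over the list alone), gclm by 0.65 ± 0.14, sqstm1 by 1.43 ± 0.29, taldo1 by 0.34 ± 0.076 and txnrd3 by 0.42 ± 0.077. The NRF2 list had a camera adjusted p of 0.00124, and adjusted p = 0.228 with an estimated correlation. Also higher were pfkma (1.13 ± 0.12), acadvl (0.64 ± 0.080), crhb (0.87 ± 0.18), vip (0.65 ± 0.10), ddit3 (0.85 ± 0.16), gad2 (0.53 ± 0.091), sdha (0.46 ± 0.077) and cyc1 (0.45 ± 0.080). Also lower were apom (−0.96 ± 0.11), apoea (−1.03 ± 0.21), slc15a1a (−0.87 ± 0.18), anxa1b (−1.33 ± 0.26) and col2a1a (−0.68 ± 0.15).

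None of the 13 mitochondrially encoded transcripts passed under the cycle (0 adjusted over the list alone), although their median was 0.174 with a camera adjusted p of 0.000448 and an adjusted p = 0.436 with an estimated correlation, in the group whose mitochondrial share was higher. Clock repressor and output genes had 0 of 23 past the threshold by limma (0 adjusted over the list alone). Their median was 0.219 with 19 of 23 above 0, a camera adjusted p of 0.000198 and an adjusted p = 0.315 with an estimated correlation. Of single genes, per2 stood at 0.69 ± 0.22 (adjusted p = 0.14), nr1d1 at 0.46 ± 0.16 (adjusted p = 0.182) and per1a at 0.05 ± 0.29 (adjusted p = 0.962), as did the light-induced cry5 at 0.62 ± 0.33 (adjusted p = 0.394). The deiodinase transcript dio3b was at −0.73 ± 0.22 (adjusted p = 0.127). With camera at its preset correlation 25 lists passed under the cycle and 21 in darkness, and 0 passed in either with an estimated correlation, while fry called 13 and 23. The cycle count leaned on single libraries: it was 86, 70 and 149 without control replicate 1, 3 or 4, and 764, 106, 77 and 175 without replicate 1, 2, 3 or 4 at 25 µM. Of 60 reported genes past the threshold, 16 held in every setting and with any library left out, among them cyp2k6, cyp2k18, arf4b, dpagt1, hspb6, me1, pfkma, ldha, ahsg2, apom and opn1mw2.

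**Figure D2:**
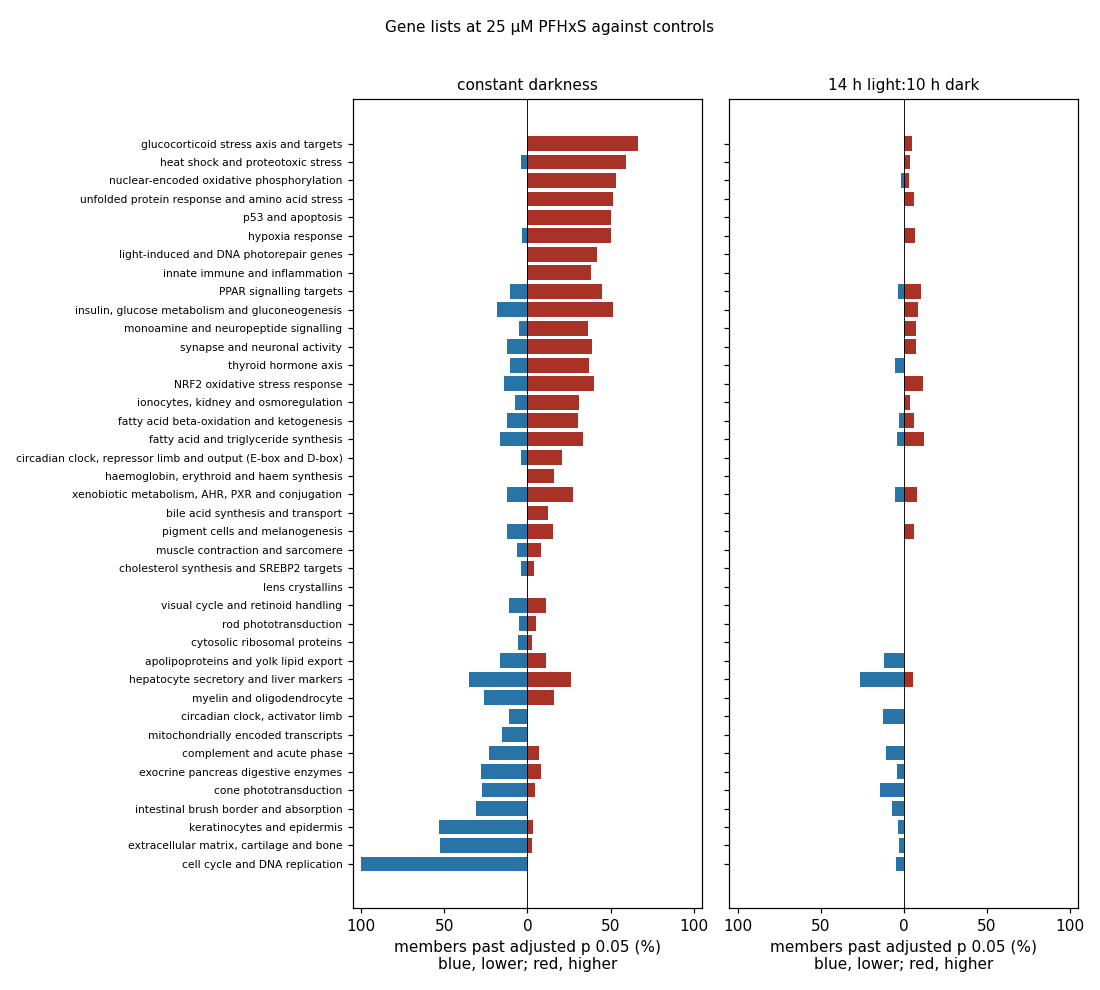
Share of measured members of 40 gene lists past an adjusted p of 0.05 at 25 µM against controls (x axis, percent; red, higher; blue, lower), in constant darkness on the left and under the light-dark cycle on the right, with lists sorted by their net share in darkness. The cell cycle bar is blue for all 41 members in darkness and for 2 of 42 under the cycle.

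The 25 µM effects of both photoperiods were then compared by gene. Across the 18270 genes tested in both, log2 fold changes at 25 µM correlated with r = 0.434 and rho = 0.45; genes are not independent replicates, and each photoperiod had its own controls. Corrected for estimation error the correlation was 0.742, and the SD of effects beyond error was 0.49 in darkness and 0.288 under the cycle. Of 324 genes past the threshold under the cycle, 303 had the same sign in darkness, and of 4092 past it in darkness, 3603 had the same sign under the cycle. Both photoperiods called 178 genes higher (26 in independent lists of these sizes) and 63 lower (11.5), and 1 gene was called in opposite directions. The 4092 genes had a median absolute log2 fold change of 0.611 in darkness, a value raised by choosing genes called there. Signed by their dark direction, their cycle median was 0.244.

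**Figure D3:**
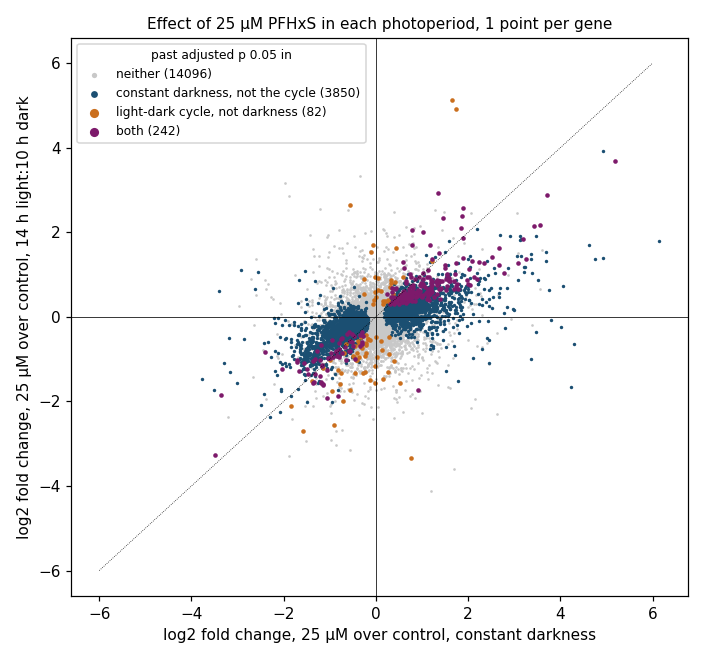
Log2 fold change at 25 µM over controls in constant darkness (x axis) and under the light-dark cycle (y axis), 1 point per gene for 18270 genes, with a dotted line where both are equal. Colours mark genes past an adjusted p of 0.05 in neither (14096), in darkness and not the cycle (3850), in the cycle and not darkness (82) or in both (242).

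A direct test of the difference between the 25 µM effects, dark minus cycle, found genes with the higher effect in darkness, through a rise in darkness, a fall under the cycle or both. The orphan receptor nr4a3 rose from 8.96 ± 0.95 to 42.9 ± 4.44 FPKM in darkness and stood at 8.61 ± 1.48 and 10.6 ± 2.15 under the cycle, a difference of 1.95 ± 0.19 on the log2 scale (SE, n = 4 per group, limma adjusted p = 1.63e-05). The difference for hamp was 3.84 ± 0.54 (adjusted p = 0.000842), with 1.43 ± 0.79 FPKM in dark controls and 15.3 ± 3.33 at 25 µM, against 42.5 ± 20.3 and 30.9 ± 6.69 under the cycle. In the other direction, arf4b had the higher effect under the cycle (−3.17 ± 0.76, adjusted p = 0.0438), with dark control 2 at 2.19 FPKM against 19.2 to 27.2 in the other dark controls. In all, 234 of 20145 genes passed, 196 with the higher effect in darkness and 38 with the lower. Of these, 158 were higher in darkness and not called under the cycle, and 29 were lower in darkness and not called under the cycle. The estimates of both photoperiods had opposite signs for 93 of 232 genes. Among the 234 genes 126 also differed between the controls, 116 of them in the direction opposite to the difference in effect, which sharing the control libraries favours.

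Positive differences, besides hamp and nr4a3, included mlycd (3.27 ± 0.76), fosl1a (3.12 ± 0.77), fosaa (3.08 ± 0.55), tagapa (3.06 ± 0.47), fosb (2.91 ± 0.55), the muscle ubiquitin ligase trim63a (2.82 ± 0.57), the tyrosine-degrading enzyme tat (2.80 ± 0.44), opn1mw2 (2.64 ± 0.35) and the vitamin D hydroxylase cyp24a1 (2.63 ± 0.54). For tat the control and 25 µM levels were 4.77 ± 0.12 and 14.5 ± 5.29 FPKM in darkness, and 13.1 ± 5.10 and 5.29 ± 1.79 under the cycle. Negative differences, besides arf4b, were in plin6 (−1.65 ± 0.36), dck (−1.57 ± 0.38), dpagt1 (−1.29 ± 0.31), lmo3 (−1.29 ± 0.31), mpp3b (−1.14 ± 0.25), sfrp1a (−0.98 ± 0.18), znf750 (−0.96 ± 0.22), apoda.2 (−0.95 ± 0.19) and tmem160 (−0.92 ± 0.22). In the synapse and neuronal activity list 11 of 41 passed, all with the higher effect in darkness (13 and 3 adjusted over the list alone), including nr4a1 (1.4 ± 0.29) and fosl2 (1.13 ± 0.23). The synapse list had a camera adjusted p of 0.049, and adjusted p = 0.634 with an estimated correlation. Glucocorticoid genes had 4 of 22 (6 adjusted over the list alone): tat, sgk1 (1.17 ± 0.26), crhb (1.1 ± 0.24) and vasopressin avp (2.32 ± 0.57). The glucocorticoid list had a camera adjusted p of 1.4e-05, and adjusted p = 0.112 with an estimated correlation. Insulin and glucose genes had 4 of 34 (9 and 1 adjusted over the list alone), such as glucose-6-phosphatase g6pca.1 (1.25 ± 0.21), igfbp1a (2.04 ± 0.41) and pfkma (0.88 ± 0.16). The insulin list had a camera adjusted p of 0.000371, and adjusted p = 0.112 with an estimated correlation. Hepatocyte genes had 5 of 34 (9 and 1 adjusted over the list alone), with agxta (0.88 ± 0.13), agxtb (1.19 ± 0.21) and fgb (0.90 ± 0.17). The hepatocyte list had a camera adjusted p of 0.00022, and adjusted p = 0.235 with an estimated correlation.

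Of 33 hypoxia genes 5 passed (10 and 1 adjusted over the list alone), including adma (1.51 ± 0.27), and the PPAR targets angptl4 (1.14 ± 0.16, adjusted p = 0.000842) and cpt1b (1.05 ± 0.18) also rose more in darkness. Thyroid genes had 3 of 20 (8 and 2 adjusted over the list alone): dio3b differed by 1.97 ± 0.27, tg by 1.56 ± 0.30 and trh by 1.11 ± 0.26. The thyroid list had a camera adjusted p of 0.0103, and adjusted p = 0.168 with an estimated correlation. Differences also passed for nfil3-6 (2.08 ± 0.37), pmchl (2.23 ± 0.49), pmaip1 (1.96 ± 0.42), ptgs2b (1.94 ± 0.43) and ptgs2a (1.32 ± 0.27). They passed as well for hspb11 (1.46 ± 0.34), crp3 (1.45 ± 0.34), pde6ha (1.35 ± 0.25), apom (0.98 ± 0.18), apoeb (0.84 ± 0.17), psat1 (0.82 ± 0.19), hif1al (0.70 ± 0.13), slc5a1 (0.63 ± 0.13) and atf4a (0.55 ± 0.13), and for comta in the other direction (−0.78 ± 0.16). None of 42 cell cycle genes passed by limma (0 adjusted over the list alone), although the median difference was −0.472 with a camera adjusted p of 1.93e-07 and an adjusted p = 0.41 with an estimated correlation. The differences for per1a (−0.08 ± 0.23), per2 (0.36 ± 0.28), nr1d1 (−0.36 ± 0.21), cry5 (−0.50 ± 0.44), pparaa (−0.25 ± 0.18), cpt1aa (−0.09 ± 0.12), pdk4 (0.58 ± 0.34), fabp10a (−0.58 ± 0.25), cyp1a (0.50 ± 0.13) and opn1lw2 (0.60 ± 0.53) did not pass (adjusted p from 0.0729 to 0.919). Camera called 20 lists here, 0 with an estimated correlation, and fry 10. Of 53 reported genes 14 held in every setting and with any library left out, among them nr4a3, hamp, tat, fosaa, fosb, tagapa, angptl4 and dio3b. With 1 library left out the call was lost in 15 fits for lmo3, 14 for dck, 13 each for arf4b, dpagt1, tmem160 and avp, 12 each for fosl1a, atf4a and trh, 10 each for sgk1 and ptgs2b, and 8 for mlycd. The direction of the calls depended on scaling: set to total fragments, 229 genes passed with 121 higher and 108 lower, against 196 and 38. The count was 137 and 140 without dark control 2 or 4, 394, 125 and 148 without dark 25 µM replicate 1, 2 or 3, and 125, 154 and 482 without cycle 25 µM replicate 1, 2 or 4.

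At 0.0025 µM in constant darkness, 4 genes of 19058 passed. The chemokine gene ccl34a.4 (chromosome 2, 40199002 to 40199780) rose from 6.90 ± 0.72 to 19.4 ± 3.88 FPKM, a log2 fold change of 1.46 ± 0.17 (SE, n = 4, limma adjusted p = 0.00843). The gene BX537263.4 (chromosome 5, 828663 to 833928) fell by 3.25 ± 0.41, from 28.1 ± 14.7 to 2.77 ± 1.32 FPKM (adjusted p = 0.0125). The ribosomal RNA gene RF00001 (chromosome 9, 358669 to 358783), for which the tables held a mean of 4.5 fragments per control library, fell by 1.89 ± 0.23 (adjusted p = 0.00976). LO018432.1 (chromosome 17, 1627379 to 1629413) was listed at 0 in all 4 dark controls and at 1.76 ± 0.72 FPKM, a mean of 3.5 fragments, at 0.0025 µM (adjusted p = 0.00176). The BX537263.4 call was lost in 3 settings and with any of 3 libraries left out. None of the 4 genes held in every setting. A limma-voom fit called 0 genes, and 1417 genes had an unadjusted p under 0.05 where chance gives 953. Without dark control 2 the count was 7. One low-dose library, replicate 4, stood apart on the second principal component of the dark libraries, at −61.8 where the other 11 lay between −17.3 and 31.7.

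Gene lists at 0.0025 µM in darkness held no member past the threshold by limma. Camera called 12 lists (7 higher, 5 lower), 0 with an estimated correlation, and fry 1. Nuclear oxidative phosphorylation genes had a median of 0.115 over 60 members, and innate immune genes 0.437 over 34. Each had 2 higher adjusted over the list alone. Their camera adjusted p were 6.24e-11 and 9.58e-08, and 0.274 for both with an estimated correlation. Medians were −0.0878 for 24 clock repressor and output genes and 0.283 for 30 complement genes (0 and 6 higher adjusted over the list alone). These had camera adjusted p of 0.000297 and 0.000753, and 0.193 and 0.403 with an estimated correlation. The genes per1a (−0.23 ± 0.087), per2 (0.03 ± 0.17), nr1d1 (−0.18 ± 0.12), pparaa (0.11 ± 0.14), cpt1aa (−0.10 ± 0.095), pdk4 (−0.23 ± 0.14), fabp10a (−0.20 ± 0.20), cyp1a (−0.09 ± 0.10), dio3b (−0.07 ± 0.14) and opn1lw2 (0.40 ± 0.28) did not pass (adjusted p from 0.609 to 0.983). The light-induced gene cry5 was below the expression filter in darkness, at 0.330 ± 0.093 FPKM in controls, 0.274 ± 0.047 at 0.0025 µM and 0.380 ± 0.16 at 25 µM.

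At 0.0025 µM under the cycle limma called 0 of 18917 genes, as did limma-voom, while 1029 had an unadjusted p under 0.05 where chance gives 946. The last count was 666 without cycle 0.0025 µM replicate 2 and 2020 without replicate 3. Simulated changes of 2-fold at this design were recovered for 65.7% of 67 genes and 4-fold changes for 86.4% of 66. The 6 genes with the smallest p were CR759907.1, an antisense transcript (chromosome 4, 69245481 to 69283666, 0.0687 ± 0.14 FPKM in controls and 1.73 ± 0.50 at 0.0025 µM, adjusted p = 0.322), the RNA exosome subunit exosc1 (0.63 ± 0.12), zgc_113232 (−0.88 ± 0.16), the splicing factors txnl4a (−0.60 ± 0.12) and snrnp40 (−0.46 ± 0.092), and ssna1 (−0.90 ± 0.18), the last 5 at an adjusted p of 0.838. The genes per1a (0.22 ± 0.29), per2 (0.30 ± 0.22), nr1d1 (−0.03 ± 0.16), cry5 (0.67 ± 0.33), pparaa (0.27 ± 0.11), cpt1aa (−0.11 ± 0.082), pdk4 (0.24 ± 0.29), fabp10a (0.11 ± 0.13), cyp1a (0.12 ± 0.092), dio3b (−0.07 ± 0.22) and opn1lw2 (−0.28 ± 0.40) had adjusted p from 0.882 to 0.989. Cell cycle genes had a median of −0.441 over 42 members, and 60 nuclear oxidative phosphorylation genes a median of −0.191. In both lists 0 passed adjusted over the list alone. Camera adjusted p were 1.12e-12 and 1.62e-15, and 0.744 for both with an estimated correlation. Camera called 14 lists (4 higher, 10 lower), 0 with an estimated correlation, and fry 0. Without cycle control 4 the count of genes was 1.

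The low-dose effects of the photoperiods differed for 1 of 20145 genes, LO018432.1 (adjusted p = 0.00158), which was listed at 0 in dark controls and at 2.44 ± 1.42 FPKM in cycle controls against 1.76 ± 0.72 and 2.24 ± 0.82 at 0.0025 µM. A limma-voom fit called 0 genes, and 1608 had an unadjusted p under 0.05 where chance gives 1007 (2558 without cycle 0.0025 µM replicate 3). The count was 2 without dark control 2 or 4, cycle control 3 or cycle 0.0025 µM replicate 4, and 10 without cycle 0.0025 µM replicate 3. Cell cycle genes had a median difference of 0.635 over 42 members (0 adjusted over the list alone, camera adjusted p = 7.85e-11, and adjusted p = 0.464 with an estimated correlation). Nuclear oxidative phosphorylation genes had a median difference of 0.319 over 61 members, of which 24 passed adjusted over the list alone and 0 over all genes. The oxidative phosphorylation list had a camera adjusted p of 5.03e-23, and adjusted p = 0.405 with an estimated correlation. Camera called 13 lists (11 higher, 2 lower), 0 with an estimated correlation, and fry 0. The differences for per1a (−0.45 ± 0.23), per2 (−0.27 ± 0.28), nr1d1 (−0.16 ± 0.21), cry5 (−0.86 ± 0.44), pparaa (−0.15 ± 0.18), cpt1aa (0.01 ± 0.12), pdk4 (−0.47 ± 0.34), fabp10a (−0.31 ± 0.25), cyp1a (−0.21 ± 0.13), dio3b (0.00 ± 0.27) and opn1lw2 (0.67 ± 0.53) had adjusted p from 0.639 to 0.999.

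Between the doses in constant darkness, 25 µM raised pth1a (6.21 ± 0.72, SE, n = 4, limma adjusted p = 8.1e-05), il11a (5.42 ± 0.78), hspb9 (5.18 ± 0.36) and cyp2k6 (4.41 ± 0.36) over 0.0025 µM and lowered he1.1 (−5.17 ± 0.75), ahsg2 (−3.04 ± 0.27) and ahsg1 (−2.78 ± 0.35). All 41 cell cycle genes were lower at 25 µM than at 0.0025 µM, also adjusted over the list alone, with a median of −1.52. The cell cycle list had a camera adjusted p of 2.16e-30, and adjusted p = 0.0883 with an estimated correlation. Further rises were in arf4b (3.67 ± 0.61), pomcb (3.66 ± 0.72), the sarcomere gene tcap (3.57 ± 0.19, adjusted p = 1.77e-07), fosl1a (3.54 ± 0.27), lepb (3.54 ± 0.68) and snai3 (3.53 ± 0.69). Dark controls of arf4b spanned 2.19 to 27.2 FPKM, so its rise here need not hold over controls. Further falls were in aqp8b (−2.73 ± 0.52), sprb (−2.63 ± 0.67), sdr42e2 (−2.62 ± 0.64), dck (−2.59 ± 0.33), cyp2aa8 (−2.58 ± 0.38), cyp2aa9 (−2.46 ± 0.38) and the antiviral gene mxc (−2.34 ± 0.50). Glucocorticoid genes had 14 of 21 higher, and hypoxia genes 18 of 32 higher and 1 lower. Adjusted over the list alone, these were 15, and 20 and 1. Their camera adjusted p were 3.86e-08 and 3.85e-09, and 0.0883 and 0.0971 with an estimated correlation. In the clock repressor and output list 8 of 24 rose (9 adjusted over the list alone, camera adjusted p = 0.000195, and adjusted p = 0.0883 with an estimated correlation), including per2 (1.01 ± 0.17), cry3b (0.66 ± 0.11) and bhlhe40 (0.48 ± 0.063). The genes pdk4 (1.52 ± 0.14) and dio3b (1.31 ± 0.14) rose, while per1a (0.20 ± 0.087), nr1d1 (0.28 ± 0.12), pparaa (−0.24 ± 0.14), cpt1aa (0.12 ± 0.095), fabp10a (0.25 ± 0.20), cyp1a (0.10 ± 0.10) and opn1lw2 (−0.42 ± 0.28) did not pass (adjusted p from 0.111 to 0.524). In all 3977 of 19058 genes passed, 2182 higher and 1795 lower, 594 and 448 of them by at least 2-fold. Scaled to total fragments the balance turned, with 1995 higher and 2122 lower. Camera called 23 lists, 0 with an estimated correlation, against 25 with fry.

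Between the doses under the cycle, arf4b (4.76 ± 0.36, SE, n = 4, limma adjusted p = 0.000115), cyp2k6 (3.68 ± 0.30), prl2 (2.69 ± 0.46) and cyp2k18 (2.37 ± 0.14, adjusted p = 1.62e-05) were higher at 25 µM than at 0.0025 µM, and ahsg2 (−2.82 ± 0.46), ponzr10 (−2.1 ± 0.32) and serpina1l (−2.07 ± 0.27) were lower. Hepatocyte genes had 13 of 34 lower and 1 higher (17 and 3 adjusted over the list alone). Nuclear oxidative phosphorylation genes had 10 of 60 higher (42 higher and 1 lower adjusted over the list alone). These lists had camera adjusted p of 9.72e-11 and 1.24e-21, and 0.132 and 0.158 with an estimated correlation. Further rises were in scd (2.33 ± 0.50), hsp70.3 (2.28 ± 0.48), g0s2 (2.27 ± 0.34), dpagt1 (2.07 ± 0.21), the vesicle fusion gene sec22ba (2.07 ± 0.24) and hspb6 (2.03 ± 0.26). Further falls under the cycle were in cbln8 (−1.92 ± 0.45), opn1mw2 (−1.90 ± 0.15), leg1.1 (−1.86 ± 0.26), ahsg1 (−1.69 ± 0.32), ccl36.1 (−1.66 ± 0.33), chia.3 (−1.62 ± 0.28) and vwa10.1 (−1.53 ± 0.28). The calls of scd, hsp70.3, cbln8 and ccl36.1 ended in a limma-voom fit, and with any of 6, 7, 8 and 5 libraries left out. That of cbln8 also ended with a pseudocount of 1. Of 21 reported genes 13 held in every setting and with any library left out. The gene cyp1a fell by 0.61 ± 0.092 (adjusted p = 0.00661), while per1a (−0.18 ± 0.29), per2 (0.39 ± 0.22), nr1d1 (0.48 ± 0.16), cry5 (−0.05 ± 0.33), pparaa (−0.15 ± 0.11), cpt1aa (0.22 ± 0.082), pdk4 (0.47 ± 0.29), fabp10a (0.52 ± 0.13), dio3b (−0.66 ± 0.22) and opn1lw2 (−0.35 ± 0.40) did not pass (adjusted p from 0.0683 to 0.965). In all 383 of 18917 genes passed, 265 higher and 118 lower, 56 and 54 of them by at least 2-fold. By list, camera called 24 lists, 0 with an estimated correlation, against 14 with fry. The count was 168, 199 and 160 without replicate 1, 2 or 4 at 0.0025 µM, and 655, 173 and 167 without replicate 1, 2 or 3 at 25 µM.

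In vehicle controls, the photoperiods were compared as dark minus cycle throughout. The period genes per1b (chromosome 7, 50822465 to 50847296), per3 and per1a were higher in darkness by log2 differences of 5.12 ± 0.13 (SE, n = 4, limma adjusted p = 6.94e-18), 4.09 ± 0.22 and 4.05 ± 0.16, and the cryptochrome cry3b (chromosome 22, 786556 to 809282) was lower by −3.71 ± 0.090, from 62.9 ± 8.54 FPKM under the cycle to 4.68 ± 0.28. Of 24 clock repressor and output genes 17 were higher and 5 lower (17 and 6 adjusted over the list alone), with a median of 2.06, a camera adjusted p of 5.36e-16 and an adjusted p = 0.0202 with an estimated correlation. They included bhlhe40 (4.09 ± 0.22), cry2 (3.62 ± 0.21), nr1d2b (2.3 ± 0.069), nr1d1 (1.38 ± 0.15) and tefa (1.38 ± 0.14), while per2 was lower (−0.90 ± 0.20). These values were set across separately scaled tables. Photoperiod and library series cannot be told apart in them or in the differences in dose effect.

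Of 9 clock activator genes 3 were higher and 3 lower (3 and 4 adjusted over the list alone), with arntl1a at −0.71 ± 0.10 and roraa at 0.62 ± 0.077. Light-induced genes had 3 of 13 higher and 4 lower, also adjusted over the list alone, with hsf2 at 1.63 ± 0.12, cry4 at −0.77 ± 0.12 and cry5 at −0.15 ± 0.31 (adjusted p = 0.771). Of 22 cone genes 10 were higher and 1 lower in darkness, also adjusted over the list alone: pde6ha (1.79 ± 0.17), grk7a (1.70 ± 0.16) and gnat2 (1.25 ± 0.14) were higher, opn1mw2 was lower (−2.33 ± 0.25), and opn1lw2 did not pass (−0.53 ± 0.37, adjusted p = 0.337). Their camera adjusted p was 1.59e-06, with an adjusted p = 0.194 with an estimated correlation. The visual cycle genes rpe65a (−1.69 ± 0.19) and rbp4 (−0.88 ± 0.094) were lower. The melatonin enzyme aanat2 (−1.56 ± 0.15) and the pigment-regulating peptides pmch (−2.5 ± 0.31) and pmchl (−3.27 ± 0.35) were lower in darkness, as was pmelb (−2.3 ± 0.24), whereas the pigment synthesis genes tyr (2.08 ± 0.16), tyrp1b (1.09 ± 0.10) and gch2 (2.1 ± 0.21) were higher.

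Xenobiotic metabolism genes were higher in dark controls for 15 of 40 members and lower for 3 (19 and 4 adjusted over the list alone), with cyp2n13 (2.08 ± 0.14), cyp2p6 (1.99 ± 0.15), abcb4 (1.90 ± 0.097), cyp2ad3 (1.5 ± 0.099) and cyp1a (0.34 ± 0.095, adjusted p = 0.0151). The list had a camera adjusted p of 1.59e-06 and an adjusted p = 0.0202 with an estimated correlation. Of 25 cholesterol synthesis genes 11 were higher and none lower, also adjusted over the list alone, such as hmgcra (2.24 ± 0.32), cyp51 (1.54 ± 0.29) and dhcr7 (0.96 ± 0.14). The cholesterol list had a camera adjusted p of 6.49e-07, and adjusted p = 0.337 with an estimated correlation. Intestinal genes had 13 of 29 higher and 2 lower (13 and 3 adjusted over the list alone), including vil1 (1.34 ± 0.15), anpepb (1.1 ± 0.11) and fabp2 (2.3 ± 0.32), and exocrine pancreas genes 9 of 25 lower (1 higher and 11 lower adjusted over the list alone), including amy2a (−2.31 ± 0.17) and cpa1 (−2.52 ± 0.20). Their camera adjusted p were 5.01e-06 and 0.000105, with an adjusted p = 0.411 and an adjusted p = 0.473 with an estimated correlation. Innate immune genes had 11 of 37 lower, also adjusted over the list alone, with tnfb (−2.38 ± 0.45), nfkbiaa (−1.35 ± 0.25) and ptgs2a (−1.27 ± 0.19). The innate immune list had a camera adjusted p of 3.19e-05, and adjusted p = 0.473 with an estimated correlation. Muscle genes had 20 of 49 lower and 3 higher (22 and 3 adjusted over the list alone), with atp2a1l at −0.91 ± 0.090, and ribosomal protein genes 26 of 69 lower and 5 higher (44 and 6 adjusted over the list alone). Their camera adjusted p were 0.000157 and 4.45e-07, with an adjusted p = 0.473 and an adjusted p = 0.637 with an estimated correlation. Cell cycle genes had 12 of 42 higher (14 adjusted over the list alone), all 4 named ones being replication licensing genes, mcm5 (1.68 ± 0.26), mcm2 (1.32 ± 0.23), mcm4 (1.28 ± 0.20) and mcm7 (0.76 ± 0.12). The cell cycle list had a camera adjusted p of 0.0361, and adjusted p = 0.838 with an estimated correlation.

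Other genes higher in dark controls were cipca (4.38 ± 0.40), usp21 (3.98 ± 0.35), slc1a2a (3.84 ± 0.29), cdc26 (3.83 ± 0.50) and fgf19 (2.83 ± 0.40). Higher too were cd36 (2.31 ± 0.13), alas1 (1.41 ± 0.15), pck1 (1.0 ± 0.17), pparg (0.84 ± 0.087), mttp (0.68 ± 0.11) and pparaa (0.45 ± 0.13, adjusted p = 0.0151). Others lower were hamp (−4.85 ± 0.38), caspbl (−3.41 ± 0.59), pth2 (−3.24 ± 0.40), the microRNA precursor dre-mir-203a (−3.23 ± 0.50) and ptgdsb.1 (−3.21 ± 0.20). Lower as well were apoda.2 (−2.87 ± 0.14), ndrg1b (−2.5 ± 0.20), gadd45ba (−1.20 ± 0.17), cdkn1a (−0.99 ± 0.16), crhb (−0.81 ± 0.17), the bile acid enzyme cyp7a1 (−0.80 ± 0.13) and dio3b (−0.74 ± 0.19). The glutamate transporter slc1a8b was listed at 0 in all 4 cycle controls and at 5.58 ± 0.86 FPKM in dark controls (adjusted p = 5.5e-11). The microRNA precursors dre-mir-133a-1 and dre-mir-2198 were listed at 0 in all 4 dark controls and at 3.99 ± 2.91 and 2.22 ± 1.76 FPKM in cycle controls (adjusted p = 0.00164 and 0.0152). The genes cpt1aa (0.00 ± 0.084), pdk4 (0.28 ± 0.24) and fabp10a (−0.08 ± 0.18) did not pass (adjusted p from 0.434 to 0.976). In all 4047 of 20145 genes passed, 1862 higher and 2185 lower in darkness, 651 and 587 of them by at least 2-fold. For lists, camera called 12 lists, 2 with an estimated correlation, against 17 with fry. The balance depended on scaling: set to total fragments, 4058 genes passed with 2515 higher and 1543 lower.

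**Figure D4:**
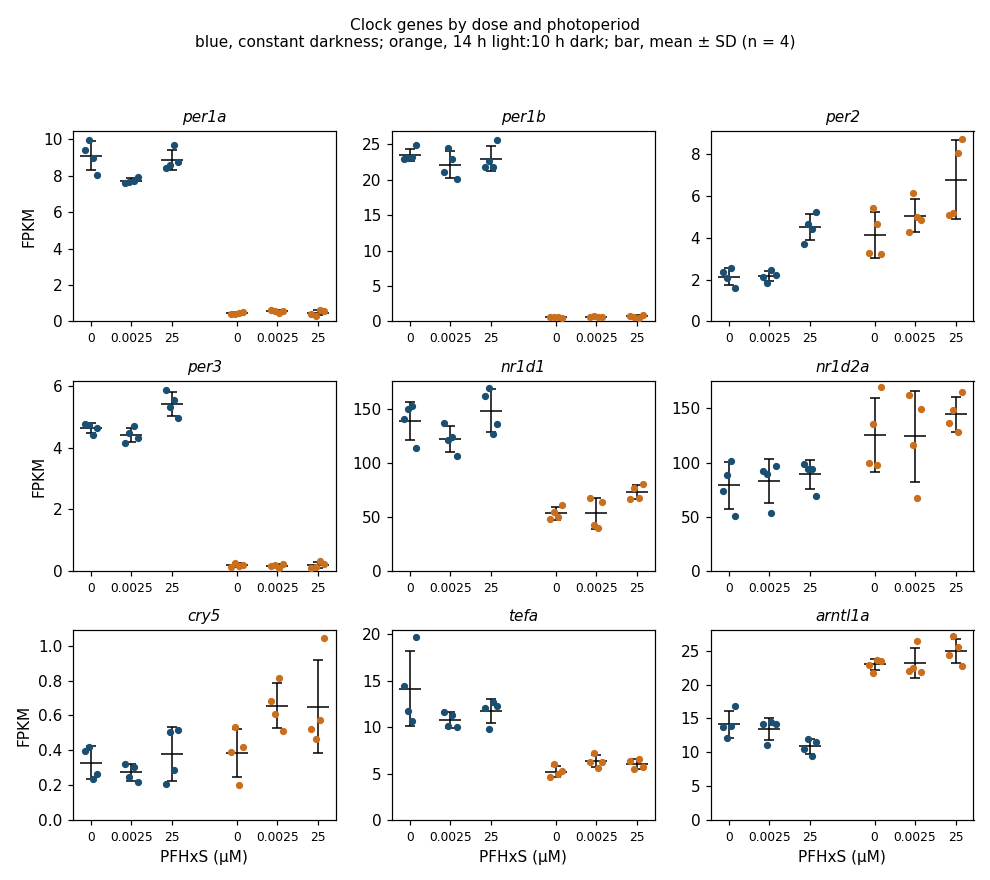
FPKM (y axis, linear, from 0) of 9 clock genes against PFHxS dose in µM (x axis), with 1 point per library, blue for constant darkness and orange for the light-dark cycle, and bars at mean ± SD (n = 4). In controls per1b stands at 23.5 ± 0.90 in darkness and 0.583 ± 0.094 under the cycle, and arntl1a at 14.1 ± 1.98 and 23 ± 0.85.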

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

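The tests of sequencing depth, of a single library, of the library series, of the scaling of the tables and of collection time, and the splits made after removing the common dose effect, were chosen after the results were seen. Single libraries stood far from the other 3 of their group in 43 of 702 gene and group pairs (6.13%), where chance gives about 35.1. There the gap to the nearest library was above 0.829 of the group's range of log2(FPKM + 0.1). Each is given as its FPKM against the range of the other 3, with that share in parentheses. The value of ponzr10 in cycle control replicate 1 was 3.21 against 2.13 to 2.23 (0.884). The value of sqstm1 in cycle control replicate 1 was 27.9 against 31.3 to 32 (0.841). The value of dio3b in cycle control replicate 1 was 5.09 against 8.27 to 9.08 (0.837). The value of rpe65a in cycle control replicate 2 was 139 against 107 to 110 (0.898). The value of slc1a2a in cycle control replicate 3 was 0.323 against 1.11 to 1.18 (0.948). The value of CR759907.1 in cycle control replicate 4 was 0.275 against 0 to 0 (1). The value of ptgdsb.1 in cycle control replicate 4 was 303 against 454 to 485 (0.858). The value of apoda.2 in cycle control replicate 4 was 781 against 1070 to 1130 (0.835). The value of g0s2 in cycle 25 µM replicate 1 was 8.88 against 13.4 to 14.3 (0.864). The value of hsp70.3 in cycle 25 µM replicate 1 was 2.76 against 15 to 20.4 (0.844). The value of rhcgb in cycle 25 µM replicate 2 was 25.5 against 17.7 to 18.9 (0.829). The value of fosb in cycle 25 µM replicate 4 was 2.46 against 0.597 to 0.765 (0.834). The value of leg1.2 in cycle 25 µM replicate 4 was 0.388 against 3.63 to 4.36 (0.919). The value of cyp1a in cycle 0.0025 µM replicate 3 was 16.6 against 18.4 to 18.8 (0.86). The value of hspb9 in dark control replicate 1 was 0.137 against 0.271 to 0.291 (0.893). The value of mcm7 in dark control replicate 1 was 45.1 against 50.1 to 50.9 (0.866). The value of anpepb in dark control replicate 1 was 64.5 against 77.3 to 79.8 (0.85). The value of il11a in dark control replicate 2 was 0.705 against 0 to 0 (1). The value of fabp2 in dark control replicate 2 was 25.3 against 19.4 to 20.2 (0.844). The value of arf4b in dark control replicate 2 was 2.19 against 19.2 to 27.2 (0.86). The value of comta in dark control replicate 3 was 26 against 25.2 to 25.2 (0.975). The value of atp2a1l in dark control replicate 3 was 390 against 340 to 346 (0.872). The value of atf3 in dark control replicate 3 was 10.5 against 7.24 to 7.7 (0.835). The value of tyrp1b in dark control replicate 4 was 145 against 130 to 131 (0.942). The value of aqp8b in dark control replicate 4 was 3.69 against 2.2 to 2.31 (0.911). The value of per1b in dark control replicate 4 was 24.9 against 22.9 to 23.2 (0.864). The value of sdha in dark control replicate 4 was 96.5 against 88.3 to 89.5 (0.852). The value of ccl34a.4 in dark control replicate 4 was 7.97 against 6.42 to 6.64 (0.842). The value of btg2 in dark control replicate 4 was 15.7 against 39.3 to 43.2 (0.906). The value of pth1a in dark control replicate 4 was 0 against 0.483 to 0.646 (0.878). The value of ier2a in dark control replicate 4 was 28.9 against 41.2 to 43.5 (0.865). The value of npas4a in dark control replicate 4 was 8.64 against 15.6 to 17.5 (0.84). The value of ccna2 in dark 25 µM replicate 1 was 2.97 against 1.38 to 1.54 (0.867). The value of prdx4 in dark 25 µM replicate 1 was 37.8 against 33.3 to 34 (0.831). The value of opn1lw2 in dark 25 µM replicate 3 was 80.2 against 149 to 166 (0.846). The value of ahsg2 in dark 25 µM replicate 4 was 0.496 against 0.22 to 0.234 (0.932). The value of sgk1 in dark 25 µM replicate 4 was 43.4 against 53.2 to 54.3 (0.91). The value of crybb1 in dark 25 µM replicate 4 was 1970 against 2070 to 2080 (0.89). The value of pth1a in dark 0.0025 µM replicate 3 was 0.645 against 0 to 0 (1). The value of RF00001 in dark 0.0025 µM replicate 4 was 1.67 against 0.937 to 0.955 (0.968). The value of cyp2aa8 in dark 0.0025 µM replicate 4 was 3.37 against 6.32 to 6.43 (0.971). The value of cyp2aa9 in dark 0.0025 µM replicate 4 was 3.28 against 5.26 to 5.62 (0.876). The value of he1.1 in dark 0.0025 µM replicate 4 was 1.82 against 6.53 to 8.36 (0.836).

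The effect of 25 µM PFHxS differed between photoperiods by a test of the difference itself (dark minus cycle, log2, n = 4 per group) for 53 named genes. It was higher in darkness for adma (1.51), agxta (0.88), agxtb (1.19), angptl4 (1.14), apoeb (0.84), apom (0.98), atf4a (0.55), avp (2.32), cpt1b (1.05), crhb (1.1), crp3 (1.45), cyp24a1 (2.63), dio3b (1.97), fgb (0.90), fosaa (3.08), fosb (2.91), fosl1a (3.12), fosl2 (1.13), g6pca.1 (1.25), hamp (3.84), hif1al (0.70), hspb11 (1.46), igfbp1a (2.04), mlycd (3.27), nfil3-6 (2.08), nr4a1 (1.4), nr4a3 (1.95), opn1mw2 (2.64), pde6ha (1.35), pfkma (0.88), pmaip1 (1.96), pmchl (2.23), psat1 (0.82), ptgs2a (1.32), ptgs2b (1.94), sgk1 (1.17), slc5a1 (0.63), tagapa (3.06), tat (2.80), tg (1.56), trh (1.11) and trim63a (2.82). It was lower in darkness for apoda.2 (−0.95), arf4b (−3.17), comta (−0.78), dck (−1.57), dpagt1 (−1.29), lmo3 (−1.29), mpp3b (−1.14), plin6 (−1.65), sfrp1a (−0.98), tmem160 (−0.92) and znf750 (−0.96). At 0.0025 µM the difference passed for LO018432.1, whose fitted value of 4.15 depends on the added 0.1 FPKM and is no bound, since the gene was listed at 0 in all dark controls.

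Other splits of the same libraries into groups of those sizes were refitted to ask if chance gives as many genes. The real split gave the most genes at 25 µM in darkness (4147, highest other 3) and under the cycle (328 and 22). It also did for 25 over 0.0025 µM in darkness (3977 and 1), under the cycle (383 and 1) and in controls (4047 and 2). Each was the only 1 of 35 as large, the lowest share possible. Effects shared by a group's libraries were not tested. Chance could not be excluded for 0.0025 µM in darkness (4 genes, highest other 13, 2 of 35) or the difference at 0.0025 µM (1 gene, highest other 2, 13 of 100). At 0.0025 µM under the cycle the count was 0 by limma and by limma-voom (unadjusted p under 0.05 for 1029 genes, highest other split 1), so all 35 splits were as large by construction and say nothing of chance. For the difference at 25 µM chance could not be excluded either (234 genes, highest other 3974, 6 of 100), and splits calling many times the real count point to a structure of the samples, the effect of dose itself. Once the dose effect common to both photoperiods was removed, the real split gave 232 genes and the highest other 9 (1 of 100).

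More genes passed at 25 µM in constant darkness than under the cycle (4147 and 328). A smaller spread between dark libraries was argued against, because enlarging dark residuals to the cycle's spread still left at least 2868 genes in 20 draws, as was a single library (at least 3139 genes with any 1 left out, against at most 764 under the cycle). Deeper sequencing was argued against too, as the median depth of the dark libraries compared was 0.722 of that of the cycle libraries. The photoperiod and the library series cannot be told apart, since 0 library series held both photoperiods. A larger response to PFHxS without light may account for the pattern and remains a hypothesis.

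Cell cycle transcripts were lower at 25 µM in darkness, with a median of −1.39 over 41 genes. Low abundance or short length was argued against, since 0 of 10000 matched random lists had a median as low (lowest −0.282). A fall of whole tissues by the same amount was argued against. The medians of 7 tissue lists were all negative, from −0.561 (keratinocytes and epidermis) to −0.038 (lens crystallins). The interquartile range of the cell cycle members was 0.194. These lists hold markers of differentiated cells, so a smaller share of dividing cells within a tissue was not tested. Stage or size varying between libraries stays open, because the separation of library scores set as its test (exact permutation p = 0.0286, the smallest that 70 permutations can give) follows from all 41 members having passed between the same groups. Reduced cell division and a delay in development of the whole exposed group may each account for the pattern, and the delay was not tested.

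Of 24 clock repressor and output genes 17 were higher and 5 lower in dark controls than in cycle controls, with a median of 2.06. The scaling of the tables was argued against, since the lowest median over the scalings was 2.06. Of members 91.7% passed in either direction, and matched random lists gave 12.5% to 45.8% (highest 62.5%). This cannot exclude a series difference shared by clock genes. The absence of light and collection at another clock time cannot be told apart, because a clock time was given for 0 samples. Free-running or desynchronised clocks in larvae raised without light may account for the pattern, as a hypothesis that these libraries leave open.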

How the results depend on the processing

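The scalings to total fragments and to median-of-ratios factors, and the tally of values with a pseudocount of 1, were chosen after the results were seen. Against a fold threshold of 1.2 the counts of genes fell to 1310 (25 µM in darkness), 41 (25 µM, cycle), 1345 and 55 (25 over 0.0025 µM in darkness and under the cycle), 42 (difference at 25 µM) and 1221 (controls), since this test asks for a larger effect. The replicate block gave 1 gene (0.0025 µM, dark), 162 (25 µM, cycle), 234 (25 over 0.0025 µM, cycle) and 147 (difference at 25 µM). Replicate numbers did not pair the libraries: 24 same-number pairs had r from −0.136 to 0.118, and a library correlated best with its own number in 9 of 48 tests, 12 by chance. With only the 2 groups compared, hence fewer libraries, the cycle gave 109 (25 µM) and 192 (25 over 0.0025 µM), and with all 24 libraries in 1 fit 671 and 672. At 0.0025 µM in darkness limma-voom called 0 genes and a mean of at least 50 fragments left 2. The difference at 0.0025 µM gave 0, 0 and 0 genes with limma-voom, at least 50 fragments and a pseudocount of 1, and 2 and 2 with no filter and total fragments. With 1 library left out, counts ranged from 3 (without dark control 1) to 7 (without dark control 2) at 0.0025 µM in darkness, 70 (without cycle control 3) to 764 (without cycle 25 µM replicate 1) at 25 µM under the cycle, 0 to 1 (without cycle control 4) at 0.0025 µM under the cycle, 160 (without cycle 0.0025 µM replicate 4) to 655 (without cycle 25 µM replicate 1) for 25 over 0.0025 µM under the cycle, 125 (without dark 25 µM replicate 2) to 482 (without cycle 25 µM replicate 4) for the difference at 25 µM, and 1 to 10 (without cycle 0.0025 µM replicate 3) for that at 0.0025 µM. The correlation of 25 µM effects between photoperiods was 0.712 over genes called in either, 0.592 over genes with at least 50 fragments, and 0.329 (without cycle 25 µM replicate 4) to 0.486 (without cycle 25 µM replicate 1). Except where a construction is named, the cause was not tested. No named gene reversed: limma-voom left 398 of 422 values on the same side of the threshold, total fragments 412, the replicate block 383, a fold threshold of 1.2 321, only the 2 groups compared 226 of 265 and leaving out 1 library 3485 of 3960. With a pseudocount of 1 the log2 value was over 1.5 times smaller for 48 of 334 called values, and 3 calls were lost. With an estimated correlation 162 list calls were lost and 2 were left, and with fry 79 were lost and 18 gained. Lists without each replicate, and the tests that need deposited counts, were not run.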

Other observations

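All tests in this part were set before the data were examined, apart from the covariances and the gene counts shared between contrasts. At 0.0025 µM cell cycle genes had a median log2 fold change of 0.129 in darkness (camera adjusted p = 0.0197, and 0.771 with an estimated correlation) and −0.441 under the cycle (1.12e-12, and 0.744 with an estimated correlation), with 0 members past the threshold by limma in either.

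The effects of both doses shared their control libraries, which alone makes them correlate. In darkness the effects at 0.0025 and 25 µM correlated with r = 0.318 over 19058 genes, where 100 simulations without any effect gave a mean of 0.498 (0.457 to 0.535). Real effects at 25 µM widen the spread and lower the observed r. The covariance was 0.0706 against 0.0598 in simulations. With separate controls for each dose r was 0.0359 (0.0231 to 0.0511 over 6 splits). Under the cycle r was 0.403 over 18917 genes, 0.501 in simulations and 0.0076 with separate controls (−0.102 to 0.0975), and the covariance was 0.0611 against 0.063. The genes called at 25 µM against controls and against 0.0025 µM, which share the 25 µM libraries, overlapped by 1753 higher and 1298 lower genes in darkness and by 137 and 70 under the cycle.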
